A study of Homo sapiens with 12 samples.

How the data were processed

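Gene expression was measured by RNA sequencing of total RNA from MDA-MB-468 cells, a human triple-negative breast cancer line, engineered so that doxycycline turns on full-length estrogen receptor beta (ERβ1, gene ESR2). Per the labels, cells were kept in phenol red-free medium with charcoal-stripped serum (10% for 3 days, then 5%). Doxycycline (50 ng/mL) was present for 48 hours in the induced groups and absent in the others. Vehicle (0.1% DMSO) or 17β-estradiol (E2, 10 nM) followed for 4 hours. The 12 libraries form 4 groups of 3, called here uninduced vehicle, uninduced E2, induced vehicle and induced E2. RNA was prepared with the RNeasy Plus kit (Qiagen) and libraries with TruSeq Sample Preparation V2, per the labels. The labels call the samples triplicates but do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

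The deposited files hold RSEM expected counts for 23228 genes, identified by gene symbol, with a further column in which the authors give each gene's fraction of transcripts, which sums to 1 in each library. The counts were used here and the fractions were not tested. RSEM 1.1.16, DESeq 1.7.10 and the hg19 genome are named in the submitters' processing notes, which do not say what DESeq was used for. The read aligner is not given in the sources used here. No genome position is given, because the annotation at hand is of another build than hg19.

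Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14541 of 23228 genes. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, leaving 8 residual degrees of freedom. The contrasts were E2 in induced cells, doxycycline without E2, E2 in uninduced cells, doxycycline with E2, and the interaction, which is the E2 change in induced cells minus that in uninduced cells. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Fold changes are given as log2 with the standard error (SE) of the fit, and levels as TMM-scaled CPM with the standard deviation (SD) over n = 3 libraries. The fitted biological coefficient of variation was 5.34%. Log2 CPM for principal components used a prior count of 2.

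Per contrast, the genes named were the 10 largest increases and the 10 largest decreases. They were taken among called genes with an average log2 CPM of at least 1 and the same sign in all 3 pairs of same-numbered libraries. ESR2 was always named, and 1 gene that the rule picks is not reported here. Of each gene list, up to 4 called members with the smallest p were eligible, or up to 2 members where none was called. This rule, the gene lists, the contrasts and the alternatives were fixed before the data were examined. Genes named outside the rule are said to be so where they appear. Some named genes share sequence with close relatives or overlap another gene, so their counts are less certain: S100A7 and S100A7A, the MT1 family, KRT6B and KRT16, the pseudogene GTF2IP1 and the read-through RTEL1-TNFRSF6B.

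Whether replicate numbers pair the samples was checked by correlating deviations from the group mean over 12376 genes. Same-numbered libraries of different groups correlated at 0.104 to 0.464 (median 0.246, 18 pairs), and differently numbered ones at −0.427 to 0.278 (median −0.220, 36 pairs). Deviations within a group cancel out, so the negative values follow from the positive ones and are no further evidence. The number, or the date that goes with it, therefore paired the samples. A model with the number as a block, with 6 residual degrees of freedom, was fitted as an alternative. The replicate number, the sequencing lane and the date in the deposited file names go together, so they cannot be fully separated: number 1 has the earlier date, and numbers 2 and 3 share the later date on different lanes.

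There were 36 gene lists, covering estrogen response and other receptors, growth signaling, cell cycle, stress, metabolism, cell types and RNA quality. Lists with at least 5 tested members (34 of 36) were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists of a contrast. Camera asks whether the members moved more in 1 direction than other genes did. Alternatives were camera with an estimated correlation, and fry. Members called are counted both after adjustment over all genes and after adjustment over the list alone.

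Further alternatives were DESeq2 1.42.0, limma-voom, upper quartile and RLE scaling, no filter, a stricter filter, only the 2 groups compared, an adjusted p under 0.01, a fold of at least 2, each library left out, each replicate number left out, the file date as a covariate, and the later date alone.

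Total expected counts per library ranged from 7.89 M to 33.3 M. A floor of 3 counts corresponds to 0.0896 to 0.375 CPM per library, and floors cover counting error only. In a test on simulated data with changes planted in 100 genes at each size, 70% to 89% of genes changed by 0.5 log2 were recovered, and 97% to 99% of those changed by 1 log2. Between 7 of 174 and 16 of 199 calls in these simulations were false.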

Results

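RNA was sequenced from 12 samples of MDA-MB-468 cells carrying ERβ1 under doxycycline control, with 3 libraries in each of 4 groups. Uninduced vehicle libraries held 7.89, 26.3 and 24.9 M counts, and uninduced E2 libraries 17.4, 33.3 and 24.9 M. Induced vehicle libraries held 12.7, 31.8 and 19.0 M, and induced E2 libraries 18, 26.2 and 22.9 M. The 10 most abundant genes took 4.38% to 4.70% of the counts of each library. On the first principal component, which held 57.9% of the variance, the 6 uninduced libraries scored −15.5 to −13.9, induced vehicle −0.72 to 5.56 and induced E2 27.2 to 29.9. The second component (13.1%) set the libraries numbered 1 (8.56 to 15.9) apart from the others (−6.79 to −4.32).

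ESR2, which encodes the induced receptor, stood at 1.30 ± 0.22 CPM (SD, n = 3) in uninduced vehicle cells and at 121 ± 11.7 CPM in induced vehicle cells. With E2 it stood at 1.61 ± 0.57 CPM in uninduced and 104 ± 10.2 CPM in induced cells. Doxycycline raised ESR2 94.0-fold without E2 (log2 6.55, SE 0.15, adjusted p = 8.06e-12) and 68.4-fold with E2 (log2 6.10, SE 0.14, adjusted p = 2.60e-12). E2 left an ESR2 difference of −0.21 log2 in induced cells (SE 0.08, adjusted p = 0.119, or 0.0003 with the replicate block and 0.0281 without induced E2 replicate 1). In uninduced cells that difference was 0.25 log2 (SE 0.30, adjusted p = 1), and the interaction was −0.46 log2 (SE 0.31, adjusted p = 0.498). The other estrogen receptor gene, ESR1, lay between 3.86 ± 0.62 CPM in induced vehicle and 4.64 ± 0.75 CPM in uninduced E2 cells.

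**Figure D1:**
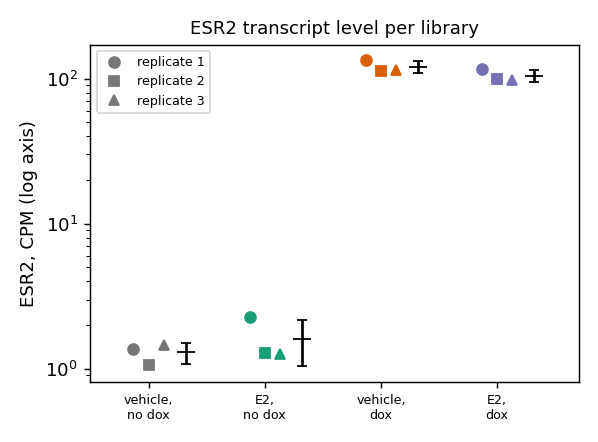
ESR2 level in CPM on a log axis for each library of the 4 groups, with points marked by replicate number and bars at the mean ± SD of 3 libraries. The induced groups average 121 and 104 CPM and the uninduced groups 1.30 and 1.61 CPM.

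Which genes respond to E2 when ERβ1 is present was asked by comparing induced E2 with induced vehicle cells (n = 3 each). EGR3, an immediate early transcription factor, rose 42.1-fold, from 1.12 ± 0.165 to 48.9 ± 5.63 CPM (log2 5.39, SE 0.14, adjusted p = 2.98e-11). THRSP, a regulator of lipid synthesis, rose by 2.94 log2 (SE 0.11). GREB1, an estrogen target linked to growth, rose from 2.88 ± 1.75 to 15.6 ± 5.19 CPM (log2 2.58, SE 0.29, adjusted p = 1.93e-05). AREG, a ligand of the EGF receptor, rose by 2.31 log2 (SE 0.38, adjusted p = 0.000557). The other 6 of the 10 largest increases, from 2.28 to 2.95 log2 with SEs of 0.13 to 0.25, were in A4GALT and MGAT3, which build cell-surface glycans, the adaptor DOK7, the RNA-binding protein RBM24, EFR3B and the phosphatase PTPRH.

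Among decreases, the secreted protease ADAMTS5 fell by 2.85 log2 (SE 0.31), from 2.02 ± 0.58 to 0.272 ± 0.159 CPM, and 1 of these libraries, at 0.114 CPM, lay under its floor of 3 counts (0.171 CPM), so this fold is less exact than its SE. Its relative ADAMTS1 fell by 1.92 log2 (SE 0.15), from 25.5 to 6.87 CPM. DKK1, a secreted Wnt antagonist, fell from 17.1 to 4.30 CPM (log2 −1.99, SE 0.41, adjusted p = 0.00349). STON1, SOX11, RASSF10, SHROOM2 and the cholesterol exporter ABCA1 fell by 1.28 to 1.64 log2. HRCT1 fell by 1.30 log2 (adjusted p = 0.0316), a call that ended without induced vehicle replicate 2 (0.217) or 3 (0.0683), or without induced E2 replicate 1 (0.0969) or 3 (0.117). HRCT1 kept its call with the replicate block.

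Estrogen-response genes rose as a group with E2 in induced cells. Of 31 tested members 24 rose and 0 fell, with a median of 0.71 log2 (25 and 2 adjusted over the list alone, 28 and 2 with the block; camera adjusted p = 1.82e-19, and adjusted p = 0.000505 with an estimated correlation). They included RAPGEFL1 at 1.72 log2, ADORA1 at 1.43 log2 and XBP1, which rose from 511 to 920 CPM. Of 33 immediate early genes 15 rose and 0 fell (16 and 1 on the list alone; adjusted p = 2.33e-07, and adjusted p = 0.00880 with an estimated correlation), among them FOS at 1.73, EGR1 at 1.19 and KLF10 at 1.01 log2. EGF and IGF pathway genes were higher as a group (12 rose and 3 fell of 22, the same on the list alone; adjusted p = 0.00129, and adjusted p = 0.0356 with an estimated correlation, or 0.0554 with the block as well). There the insulin receptor substrate IRS2 rose from 42.0 to 183 CPM, TGFA rose by 1.17 log2 and IGFBP3, which binds IGF, fell by 1.02 log2. Of 18 genes of the unfolded protein response, which restores folding in the endoplasmic reticulum, 13 rose and 0 fell (16 and 0 on the list alone), including DNAJB9 at 0.84 and HERPUD1 at 0.39 log2. Their adjusted p was 1.59e-10, and adjusted p = 0.0633 with an estimated correlation.

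Glucocorticoid and androgen response genes were also higher with E2 in induced cells (7 rose and 2 fell of 14; 9 and 3 on the list alone; adjusted p = 0.00319, and adjusted p = 0.0499996 with an estimated correlation, or 0.156 with the block as well), with GLUL at 0.84 and FKBP5 at 0.63 log2. Of 27 ATF4 targets, which respond to amino acid shortage, 9 rose and 0 fell (10 and 0 on the list alone). With the replicate block 15 rose and 2 fell. The ATF4 list had adjusted p = 0.00569, and adjusted p = 0.849 with an estimated correlation. Its amino acid transporter genes SLC7A5 and SLC3A2 rose by 1.16 and 0.62 log2. The other 28 lists given to camera had no call. Single members of these rose, including WNT4 at 1.83 log2, the cytokine LIF at 1.74, the YAP target CYR61 at 1.32, the glycolytic regulator PFKFB3 at 1.31, the cell-cycle inhibitor CDKN1A at 0.92 and the adhesion gene CDH1 at 0.91. VWF, an endothelial marker with an average log2 CPM under 1, rose by 2.91 log2, a fold that is less exact at so low a level. Members that fell included the coregulator NCOA7 at −0.75, the integrin ITGB4 at −0.69, the retinoid receptor RARG at −0.53 and the glucocorticoid receptor NR3C1 at −0.51 log2.

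In all, edgeR called 2394 genes for E2 in induced cells, of which 1433 rose and 961 fell, and 217 rose and 50 fell by at least 2-fold. The number that fell was 609 without induced vehicle replicate 2 and 1497 with the block, and upper quartile scaling gave 1258 higher and 1206 lower.

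**Figure D2:**
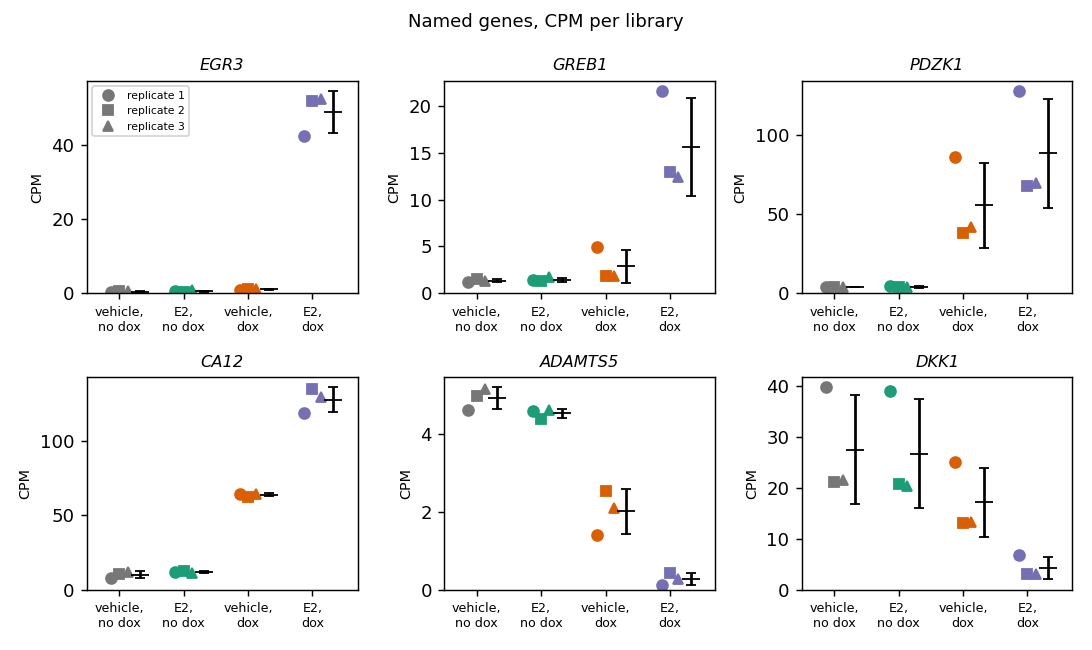
Level in CPM of EGR3, GREB1, PDZK1, CA12, ADAMTS5 and DKK1 in each library of the 4 groups, with bars at the mean ± SD of 3 libraries. EGR3 averages 48.9 CPM in induced E2 and 1.12 CPM in induced vehicle cells, and PDZK1 averages 55.7 CPM already in induced vehicle cells.

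What induction changes without added E2 was asked by comparing induced vehicle with uninduced vehicle cells (n = 3 each). After ESR2, the scaffold gene PDZK1 had the largest increase, from 4.05 to 55.7 ± 26.7 CPM (log2 3.75, SE 0.40). CA12, a membrane carbonic anhydrase, rose from 10.2 to 63.9 CPM (log2 2.57, SE 0.09, adjusted p = 9.54e-10). THRSP rose by 3.14 log2 (SE 0.20) and keratin KRT13 by 2.67 log2 (SE 0.43). The surface marker CD34, the kinase MAPK4, complement C3 and the related S100A7A and S100A7 rose by 1.77 to 2.56 log2. The ceramidase gene ACER1 fell from 41.2 to 10.8 CPM (log2 −1.93, SE 0.07). NOV and CTGF, which encode matrix signaling proteins, fell by 1.60 (SE 0.23) and 1.21 log2 (SE 0.20). ADAMTS5 fell by 1.23, the stress-responsive NDRG1 by 0.99 and the VEGF receptor KDR by 0.97 log2.

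Another 4 of these 10 largest decreases were less secure in the fit without the replicate block. With the block all 4 kept their call, and each fell in all 3 same-numbered pairs. STON1 (−1.15 log2, adjusted p = 0.00846) was no longer called without uninduced vehicle replicate 2 (0.0596) or 3 (0.0509), and GTF2IP1 (−0.98 log2) without replicate 3 of that group (0.0542). The protease MMP7 (−1.07 log2, adjusted p = 0.0427) was not called by DESeq2 (0.0868). Its call also ended without uninduced vehicle replicate 2 (0.149) or 3 (0.190), or induced vehicle replicate 1 (0.0993), 2 (0.0617) or 3 (0.0816). The carbonic anhydrase CA2 (−1.05 log2, adjusted p = 0.0492) was not called by DESeq2 (0.168). Without uninduced vehicle replicate 2 or 3 its adjusted p was 0.196 or 0.174, and without induced vehicle replicate 1 or 2 it was 0.107 or 0.124.

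Estrogen-response genes rose with induction alone. Of 31 members 17 rose and 0 fell, with a median of 0.44 log2 (20 and 2 on the list alone and with the block; adjusted p = 7.03e-19, and adjusted p = 0.000566 with an estimated correlation), including RAPGEFL1 at 1.40, MYB at 0.71 and XBP1 at 0.62 log2. The interferon-stimulated list, of antiviral genes, was higher with a median of 0.36 log2 (4 rose and 0 fell of 25; 14 and 0 on the list alone; adjusted p = 3.67e-09, and adjusted p = 0.465 with an estimated correlation). With the replicate block 23 of its members rose. BST2 rose by 0.36 log2 (adjusted p = 0.00610) and DDX58 by 0.58 log2 (adjusted p = 0.0103, but 0.0688 without uninduced vehicle replicate 2). Interferon-stimulated genes were also lower in the libraries of later date, with a median of −0.35 log2 and 24 of 25 members lower (camera adjusted p = 2.50e-19, and adjusted p = 0.181 with an estimated correlation). The list of NRF2 targets and metallothioneins, which respond to oxidants and metals, was higher (5 rose and 1 fell of 14; 8 and 1 on the list alone), with MT1X at 0.66, MT2A at 0.54 and MT1E at 0.44 log2. Its adjusted p was 0.000114, and adjusted p = 0.337 with an estimated correlation.

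Genes of basal and squamous cells fell as a group without E2 (1 rose and 8 fell of 18; 2 and 10 on the list alone; adjusted p = 1.15e-05, and adjusted p = 0.102 with an estimated correlation). The basal keratins KRT6B, KRT14, KRT16 and KRT5 fell by 0.86, 0.81, 0.68 and 0.51 log2. S phase genes, of DNA replication, were lower as a group (0 rose and 2 fell of 30; 0 and 16 on the list alone; 13 fell with the block and 4 under upper quartile scaling; adjusted p = 5.12e-11, and adjusted p = 0.102 with an estimated correlation). The 2 called, GINS2 at −0.21 and MCM4 at −0.15 log2, both lost the call when any of the 6 libraries compared was left out (adjusted p 0.0524 to 0.135). G2 and M phase genes were lower (0 rose and 3 fell of 26; 0 and 7 on the list alone; 6 fell with the block), with UBE2C at −0.28 log2. Their adjusted p was 1.29e-07, and adjusted p = 0.337 with an estimated correlation.

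Invasion and matrix genes were lower without E2 (0 rose and 4 fell of 24; 0 and 5 on the list alone; 7 fell with the block), with ADAMTS1 at −0.73 log2. Their adjusted p was 0.0183, and adjusted p = 0.113 with an estimated correlation, or 0.0966 without the libraries numbered 2. The unfolded protein response was higher (2 rose and 0 fell of 18; 3 and 0 on the list alone; 4 rose with the block and 1 under upper quartile scaling) at adjusted p = 0.00764, and adjusted p = 0.434 with an estimated correlation. That call ended without the libraries numbered 2 (0.0902) or 3 (0.0954). The list of histone genes and nuclear RNAs, which served as a sign of RNA quality, was higher at adjusted p = 0.0391 with 0 of 10 members called by edgeR, or 1 with the block. Their adjusted p was 0.434 with an estimated correlation, 0.205 without the libraries numbered 1 and 0.0966 without those numbered 2. Outside the called lists, WNT4 rose by 1.31, IGFBP5 by 1.24 and PFKFB3 by 0.88 log2, and IGFBP3 fell by 0.80 log2.

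In all, 554 genes were called for doxycycline without E2, of which 355 rose and 199 fell, and 62 rose and 12 fell by at least 2-fold. With the replicate block 1456 were called (805 rose and 651 fell), among them all 554. Without uninduced vehicle replicate 2 the count was 364 (111 fell), and without replicate 3 it was 369 (112 fell). The number that fell was 125 without induced vehicle replicate 1, 113 without replicate 3 of that group and 128 with only the 2 groups compared.

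Whether E2 acts without induced ERβ1 was asked by comparing uninduced E2 with uninduced vehicle cells (n = 3 each). EGR3 stood at 0.574 CPM with E2 and 0.486 CPM with vehicle. The estrogen-response list had a median of 0.01 log2 and a camera adjusted p of 0.934. With edgeR 0 genes were called and 227 had an unadjusted p under 0.05, where evenly spread p-values would give 727. With the replicate block the numbers were 0 and 451. Counts under 727 are no added evidence that E2 had no effect. The fit without the block includes the spread between numbers. Its biological coefficient of variation was 5.34%, against 2.90% with the block. Limma-voom called 0 genes. DESeq2 called 1, RPL21 (adjusted p = 0.00501), a gene singled out after its values were seen, with 121 counts in uninduced E2 replicate 3 and 0 in the other 5 libraries. Without uninduced vehicle replicate 2, edgeR called 1 gene, the pseudogene ZNF321P (adjusted p = 0.0231), also singled out after its values were seen.

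In uninduced cells 4 lists passed camera with 0 members called by edgeR, and none of these 4 passed with an estimated correlation. Ribosomal protein genes were higher with E2 (adjusted p = 0.00298, and adjusted p = 0.870 with an estimated correlation), but not without the libraries numbered 2 (0.296). Interferon-stimulated genes were higher (adjusted p = 0.0314, and adjusted p = 0.870 with an estimated correlation), but not without those numbered 2 (0.406). Coregulators of nuclear receptors were lower (adjusted p = 0.0314, and adjusted p = 0.870 with an estimated correlation), but not without those numbered 2 (0.586) or 3 (0.164). Notch pathway genes were lower (adjusted p = 0.0238, and adjusted p = 0.793 with an estimated correlation), but not without those numbered 1 (0.0607) or 2 (0.296).

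What induction changes in the presence of E2 was asked by comparing induced E2 with uninduced E2 cells (n = 3 each). EGR3 rose by 6.42 log2 (SE 0.15), THRSP by 5.71 (SE 0.15) and CD34 by 4.88 (SE 0.19). MGAT3, PDZK1, MAPK4, KRT13 and RBM24 rose by 3.42 to 4.48 log2, and GREB1 had the next largest increase. Decreases were led by ADAMTS5 at −3.94 log2 (SE 0.27), STON1 at −2.74 (SE 0.27), DKK1 at −2.66 (SE 0.39) and ADAMTS1 at −2.63 (SE 0.14). HRCT1, NOV, PPP1R3C, SOX11, RASSF10 and FOXQ1 fell by 1.87 to 2.08 log2. In all 4078 genes were called, of which 2184 rose and 1894 fell, and 424 rose and 155 fell by at least 2-fold. Under upper quartile scaling 1799 rose and 2679 fell.

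Of 31 estrogen-response genes 26 rose and 1 fell with induction in the presence of E2, with a median of 1.24 log2 (the same on the list alone; adjusted p = 1.34e-21, and adjusted p = 0.000343 with an estimated correlation). CA12 rose by 3.39, RAPGEFL1 by 3.05 and XBP1 by 1.42 log2. Immediate early genes were higher (16 rose and 4 fell of 33; 17 and 4 on the list alone; adjusted p = 0.000537, and adjusted p = 0.0436 with an estimated correlation), with SPRY4 at 1.83 log2. EGF and IGF pathway genes were higher (11 rose and 3 fell of 22; 13 and 3 on the list alone; adjusted p = 0.000969, and adjusted p = 0.0436 with an estimated correlation), though IGFBP3 fell, at −1.80 log2. With the block and an estimated correlation neither of these 2 lists passed, at 0.0836 for immediate early and 0.0787 for EGF and IGF genes. The unfolded protein response was higher (15 rose and 0 fell of 18; 17 and 0 on the list alone; adjusted p = 1.73e-09, and adjusted p = 0.103 with an estimated correlation). NRF2 and metallothionein genes were higher (7 rose and 2 fell of 14; 8 and 2 on the list alone; adjusted p = 0.00309, and adjusted p = 0.493 with an estimated correlation).

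Basal and squamous genes were lower with induction in the presence of E2 (2 rose and 10 fell of 18; 2 and 11 on the list alone; adjusted p = 0.000537, and adjusted p = 0.138 with an estimated correlation). S phase genes were lower (1 rose and 6 fell of 30, the same on the list alone; 1 and 11 with the block, 1 and 12 under upper quartile scaling). Their adjusted p was 0.0177, and adjusted p = 0.582 with an estimated correlation, or 0.0678 without the libraries numbered 2. Ribosomal protein genes were lower (0 rose and 4 fell; 0 and 0 on the list alone; 14 fell with the block), at adjusted p = 0.00494, and adjusted p = 0.649 with an estimated correlation. The number that fell was 1 under RLE and 16 under upper quartile scaling. Without the libraries numbered 2 or 3 that p was 0.117 or 0.0634. Interferon-stimulated genes were higher (3 rose and 0 fell of 25; 2 and 0 on the list alone; 22 rose with the block), at adjusted p = 0.0142, and adjusted p = 0.844 with an estimated correlation. Without the libraries numbered 2 it was 0.0799, and this list was lower at the later date, as given above.

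Further lists had called members but no camera call with induction in the presence of E2, with the list's adjusted p in parentheses. They included TGF-beta and BMP pathway genes (8 rose and 8 fell of 28, p 0.988), Wnt genes (7 and 7 of 22, p 0.988), with WNT4 at 3.25 log2, nuclear receptors, ESR2 itself included (4 and 6 of 19, p 0.988), and Notch genes (6 and 6 of 20, p 0.854). Cell-cycle inhibitors (6 and 8 of 19, p 0.867), p53 targets (2 and 7 of 20, p 0.328), G2 and M phase genes (2 and 4 of 26, p 0.340) and BCL2 family genes (5 and 2 of 17, p 0.379) were others. Among metabolic lists these were glycolysis and hypoxia (8 and 4 of 23, p 0.340), fatty acid synthesis (6 and 2 of 18, p 0.565), cholesterol synthesis (5 and 2 of 23, p 0.565) and mitochondrial respiration (2 and 4 of 32, p 0.867). Among stress lists were ATF4 targets (7 and 0 of 27, p 0.193), with SLC7A5 at 1.68 log2, heat shock (4 and 1 of 15, p 0.340), NF-kB (4 and 2 of 16, p 0.532) and aryl hydrocarbon receptor targets (2 and 2 of 14, p 0.867). YAP targets (5 and 6 of 17, p 0.798), glucocorticoid and androgen response (7 and 4 of 14, p 0.124) and coregulators (5 and 2 of 18, p 0.379) had no call either. Epithelial and luminal (8 and 4 of 21, p 0.357), mesenchymal (4 and 5 of 14, p 0.565) and invasion genes (4 and 5 of 24, p 0.318) likewise had none. With the replicate block the counts were 8 and 4 for coregulators, 4 and 9 for G2 and M phase, 10 and 4 for ATF4 targets, 6 and 4 for NF-kB, 4 and 4 for aryl hydrocarbon receptor targets and 4 and 10 for invasion genes. They were 10 and 7 for glycolysis and hypoxia, 7 and 4 for fatty acid synthesis and 5 and 2 for heat shock. Under upper quartile scaling they were 4 and 4 for coregulators, 2 and 8 for G2 and M phase, 3 and 8 for cell-cycle inhibitors, 3 and 6 for YAP targets, 7 and 2 for ATF4 targets, 3 and 3 for fatty acid synthesis, 3 and 2 for heat shock, 1 and 6 for mitochondrial respiration and 2 and 6 for mesenchymal genes.

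Markers of other cell types had no camera call with induction in the presence of E2. Of 5 endothelial markers VWF, at its low level, rose by 4.00 and KDR fell by 1.22 log2 (list adjusted p = 0.532). Of 5 myoepithelial markers 0 were called by edgeR (list adjusted p = 0.391), and the 3 leukocyte markers tested were not called either. Of these, 1 myoepithelial marker fell with the block and 1 under upper quartile scaling, and with the block 1 leukocyte marker rose, 1 leukocyte marker fell and 1 fibroblast marker fell. Of 4 fibroblast markers FAP was called at 0.33 log2, though not without uninduced E2 replicate 2 (0.0810) or 3 (0.181), or induced E2 replicate 1 (0.134), 2 (0.0506) or 3 (0.0867), nor under upper quartile scaling (0.0715). Of the 10 RNA quality genes 0 were called (list adjusted p = 0.532).

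**Figure D3:**
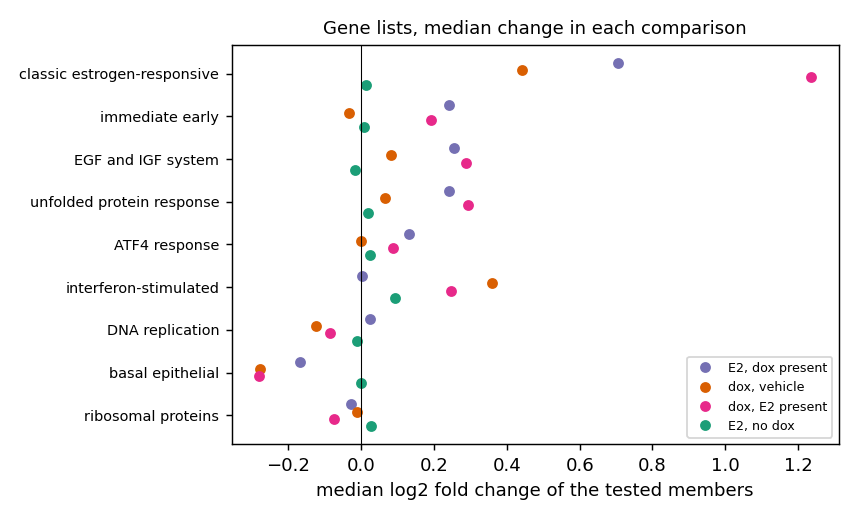
Median log2 fold change of the tested members of 9 gene lists in the 4 comparisons of 2 groups. The estrogen-response median is 0.71 for E2 in induced cells, 0.44 for doxycycline without E2, 0.01 for E2 in uninduced cells and 1.24 for doxycycline with E2.

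Whether the E2 response differs between induced and uninduced cells was tested by the interaction. EGR3 had the largest positive interaction, 5.27 log2 (SE 0.45), followed by A4GALT at 2.95 (SE 0.34) and MGAT3 at 2.81 (SE 0.30). The EGR3 level in uninduced vehicle replicate 1, 0.375 CPM, lay at that library's floor of 3 counts, so its value is less exact than its SE. EFR3B, RBM24, DOK7, THRSP, GREB1, CD34 and PTPRH had values of 2.31 to 2.80 log2. On the negative side stood ADAMTS5 at −2.71 (SE 0.36) and ADAMTS1 at −1.90 log2 (SE 0.19), with SOX11, RASSF10 and PPP1R3C between −1.38 and −1.29. DKK1 had −2.01 log2 (SE 0.52, adjusted p = 0.0267), a call that ended without uninduced vehicle replicate 2 (0.0724) or 3 (0.0722), or induced E2 replicate 2 (0.0928) or 3 (0.0867). STON1 had −1.59 log2 (adjusted p = 0.0127), with calls ending without induced vehicle replicate 2 (0.0625) or induced E2 replicate 3 (0.0502). SHROOM2 had −1.47 log2 (adjusted p = 0.0176), not called without induced vehicle replicate 2 (0.0641) or 3 (0.0541). RTEL1-TNFRSF6B had −1.29 log2 (adjusted p = 0.0196), not called without uninduced vehicle replicate 2 (0.0597), uninduced E2 replicate 3 (0.0550) or induced E2 replicate 2 (0.0598). DKK1, STON1, SHROOM2 and RTEL1-TNFRSF6B kept their calls with the replicate block.

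Estrogen-response genes had positive interactions (20 positive and 0 negative of 31; 22 and 0 on the list alone; adjusted p = 5.11e-20, and adjusted p = 0.000455 with an estimated correlation). Immediate early genes did as well (10 and 0 of 33; 13 and 1 on the list alone; adjusted p = 3.08e-07, and adjusted p = 0.00931 with an estimated correlation). EGF and IGF pathway genes (10 and 3 of 22, the same on the list alone) had adjusted p = 0.00334, and adjusted p = 0.0515 with an estimated correlation. Unfolded protein response genes (8 and 0 of 18; 12 and 0 on the list alone) had adjusted p = 3.01e-09, and adjusted p = 0.0876 with an estimated correlation. Glucocorticoid and androgen response genes (5 and 2 of 14; 8 and 3 on the list alone) had adjusted p = 0.0106, and adjusted p = 0.0839 with an estimated correlation. Ribosomal protein genes had negative interactions as a set with 0 members called by edgeR, at adjusted p = 0.0156, and adjusted p = 0.808 with an estimated correlation. Without the libraries numbered 2 or 3 that p was 0.145 or 0.0765. With the replicate block ATF4 targets passed too (0.00263 against 0.0766, and adjusted p = 0.200 with the block and an estimated correlation). Interferon-stimulated genes then passed with negative interactions (1 positive and 6 negative of 25, 0.0193 against 0.295, and adjusted p = 0.768 with the block and an estimated correlation).

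In all, 1232 genes were called for the interaction, 823 positive and 409 negative, of which 165 and 39 reached 2-fold. With the replicate block 2143 were called (1288 positive and 855 negative), among them all 1232. Without induced vehicle replicate 2 there were 267 negative, and upper quartile scaling gave 700 positive and 518 negative.

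**Figure D4:**
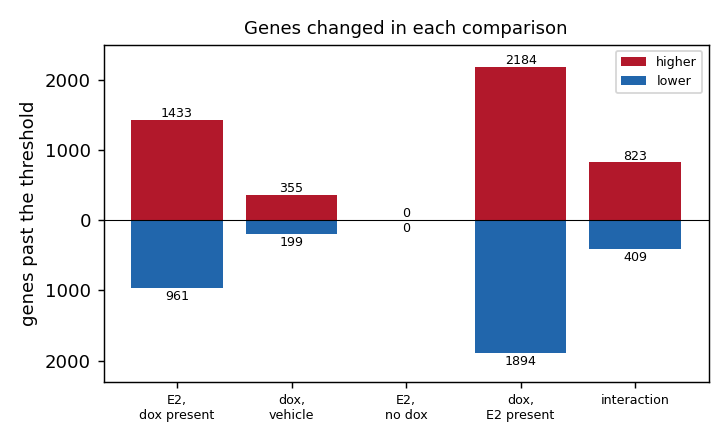
Number of genes called higher and lower at an adjusted p under 0.05 in each comparison and for the interaction. The totals are 2394 for E2 in induced cells, 554 for doxycycline without E2, 0 for E2 in uninduced cells, 4078 for doxycycline with E2 and 1232 for the interaction.

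The 2 doxycycline comparisons share no library, so their calls can be set against each other. Of 355 genes that rose without E2, 322 also rose with E2, where independence gives 53.3 (Fisher's exact test, 1-sided, p = 1.45e-230), and 4 fell. Of 199 that fell without E2, 167 also fell with E2, where independence gives 25.9 (Fisher's exact test, 1-sided, p = 3.45e-116), and 6 rose. Fisher's test treats genes as independent draws, and both sets of calls come from the same fit. Its p-values therefore do not measure the spread between samples. CA12, PDZK1, THRSP and CD34 are among those that rose in both, and ADAMTS5 and NOV among those that fell in both.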

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

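Apart from the test of library depth, the tests that weigh the 3 patterns below were chosen only after the result was seen. The difference between groups that drew attention was the interaction itself, in which the E2 change in induced cells departed from that in uninduced cells for 823 genes upward and 409 downward. The genes concerned were EGR3 (5.27 log2), A4GALT (2.95), MGAT3 (2.81), EFR3B (2.80), RBM24 (2.78), DOK7 (2.73), THRSP (2.57), GREB1 (2.52), CD34 (2.32) and PTPRH (2.31). On the negative side they were ADAMTS5 (−2.71), DKK1 (−2.01), ADAMTS1 (−1.90), STON1 (−1.59), SHROOM2 (−1.47), SOX11 (−1.38), RASSF10 (−1.37), PPP1R3C (−1.29) and RTEL1-TNFRSF6B (−1.29). Of these, DKK1, STON1, SHROOM2 and RTEL1-TNFRSF6B lose the call without single libraries, named in the report, with adjusted p up to 0.0928, 0.0625, 0.0641 and 0.0598. With the replicate block they keep it. Median interactions of the lists were 0.65 log2 for estrogen response, 0.29 for glucocorticoid and androgen response, 0.20 for immediate early genes, 0.23 for EGF and IGF pathway genes, 0.23 for the unfolded protein response and −0.0565 for ribosomal protein genes. With an estimated correlation the adjusted p was 0.0839 for glucocorticoid and androgen response, 0.0515 for EGF and IGF, 0.0876 for the unfolded protein response and 0.808 for ribosomal genes, so these 4 calls end. The ribosomal call also ends without the libraries numbered 2 (0.145) or 3 (0.0765).

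For the interaction, 5 of 100 relabelings of the 12 libraries into 4 groups of 3, the real one included, called at least 1232 genes, and the highest other was 2286. All 3 induced E2 libraries stood on 1 side of the contrast in 23 relabelings, among them all 5 that reached 1232. The other 4 of these 5 thus carry the difference of the induced E2 libraries themselves. For that reason the count cannot decide whether chance gave the interaction. The relabelings did not keep the replicate numbers together, and the median of the others was 0. For the comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real count was 2394 for E2 in induced cells (1 of 10 splits reached it), 554 for doxycycline without E2 (1 of 10), 0 for E2 in uninduced cells (10 of 10) and 4078 for doxycycline with E2 (1 of 10), and the highest other was 0 in each.

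Genes changed by doxycycline without E2 tended to move the same way when E2 was added: of 553 called genes without ESR2, 79.6% had the same sign, against 44.2% in simulations with no E2 effect. Shared control libraries alone would make the covariance of the 2 changes negative (−0.00598 in simulation), but it was 0.0193. Doxycycline acting without the receptor was predicted to leave the set unmoved by E2, but the median E2 change in the direction of the doxycycline change was 0.282 log2. This does not exclude such a route, because E2 acting through the induced receptor could also move genes that doxycycline changed otherwise. Doxycycline acting without the receptor stays open, also for the 206 genes not called with E2, since no library had doxycycline without the transgene. A candidate explanation is receptor activity before E2 was added, and these data cannot separate unliganded receptor from traces of estrogen in the medium.

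Interferon-stimulated genes were higher with doxycycline (adjusted p = 0.465 without E2 and 0.844 with E2 under an estimated correlation), though the same list was lower at the later file date (median −0.35 log2, 24 of 25 members lower, camera adjusted p = 2.50e-19, and adjusted p = 0.181 with an estimated correlation). Within each replicate number the list median rose with doxycycline, at least by 0.143 log2 over 6 such differences. E2 in uninduced cells, where edgeR called no gene, moved it by 0.14005, 0.13592 and 0.00291 log2 in numbers 1, 2 and 3. The smallest doxycycline rise was thus close to changes seen without induction. Means over the numbers were 0.374 log2 (SD 0.08995) for doxycycline without E2 and 0.249 (SD 0.0976) with E2. For E2 in uninduced cells the mean was 0.09296 log2 (SD 0.07801). Each difference lies within a single date, so the date is excluded as the whole cause. Under RLE and upper quartile scaling the lowest list median was 0.218 log2 with the replicate block and 0.205 log2 without it. Scaling is therefore excluded as well. For receptor activity that E2 raises within 4 hours, the bound was a lift of at least 0.0935 log2 (0.25 of the doxycycline change). This bound was set after the result was seen. In induced cells the E2 change of the list median was 0.0232, −0.0147 and −0.0912 log2 in the 3 numbers (mean −0.0276, SD 0.0583). All 3 values lay under 0.0935. The test required the mean plus 1 SD to do so too, both over the numbers and over the members. The SD over the 25 members was 0.164, which puts 0.0935 within 1 SD, so the test cannot decide. A rise of single members also stays open. Doxycycline itself could account for the 0.374 log2 without E2, because no doxycycline-treated cells lacked the transgene.

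The libraries numbered 1 differed from those numbered 2 and 3 in 2601 genes, 1451 higher and 1150 lower at the later date. After thinning every library to the depth of the shallowest, 1756 genes were still called and 1624 of them were in the full set, so depth is excluded as the whole cause. A difference between lanes alone would also part numbers 2 and 3, which differed in 11 genes against 1814 between numbers 1 and 2 and 1690 between numbers 1 and 3. Culture, library or sequencing day may each be the source of the 1814, and they cannot be separated here. No biological explanation was tested for this pattern, since the groups are spread evenly over the numbers.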

How the results depend on the processing

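ESR2 was called upward under every alternative run, at 6.37 to 6.72 log2 without E2 and 5.94 to 6.34 with E2. Of 443 called results for named genes, 378 kept their call in every alternative, 0 reversed, 65 lost it when some library was left out and 30 in another setting. Apart from ESR2 for E2 in induced cells, the replicate block changed no call of a gene that the report names in that comparison, and it kept 2393 of 2394 calls for E2 in induced cells and 4073 of 4078 for doxycycline with E2. It raised the counts to 1456 for doxycycline without E2 and 2143 for the interaction, as did the date as a covariate (1451 and 2146) and the later date alone (1082 and 2105). Removing the spread between numbers is what the block does; for the later date alone the cause was not tested. A fold of at least 2 leaves, by its construction, 267, 74, 579 and 204 genes for E2 in induced cells, doxycycline without and with E2, and the interaction. An adjusted p under 0.01 leaves 1528, 296, 2754 and 696. Leaving out 1 library gave 364 to 472 genes for doxycycline without E2 and 0 to 1 for E2 in uninduced cells, where DESeq2 called 1. Genes shared by the doxycycline comparisons numbered 683 up and 522 down with the block, and 208 and 71 at an adjusted p under 0.01. Lists passing the set test with an estimated correlation numbered 1 for doxycycline without E2, 0 for E2 in uninduced cells, 3 for doxycycline with E2 and 2 for the interaction. With fry there were 0 for E2 in uninduced cells and 21 for doxycycline with E2, and leaving out a number gave 0 to 4 for E2 in uninduced cells; the cause was not tested. Of the lists that passed fry, 2 without a camera call had the opposite direction there, nuclear receptors for doxycycline without E2 (0.0312) and Wnt genes for doxycycline with E2 (0.0211). The nuclear receptor list includes the induced ESR2 itself, and its mean of 0.29 log2 lay above its median of −0.05 log2. No list test was run without ESR2, and for the Wnt genes the cause was not tested. Depth limits the low genes, since 3 counts are 0.375 CPM in the shallowest library.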

Other observations

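The sets of genes in this part, the simulation and the tests between dates were chosen only after the values were seen; some members, such as PDZK1, were also picked by the planned naming rule. Of the genes changed by doxycycline without E2, 37 moved the opposite way when E2 was added to induced cells. The neurotrophin receptor NTRK2 fell by 0.90 log2 with doxycycline and rose by 1.78 with E2. NDRG1 fell by 0.99 and rose by 1.05, SPON2 fell by 0.62 and rose by 0.83, and SYTL4 fell by 0.75 and rose by 0.61. In the other direction, the retinol dehydrogenase RDH10 rose by 0.68 and fell by 1.17, the pioneer factor FOXA1 rose by 0.37 and fell by 0.70, and the KIT ligand KITLG rose by 0.51 and fell by 0.66. The induced vehicle libraries enter both changes with opposite sign, which by itself favors opposite signs. With E2 effects simulated only outside the genes changed by doxycycline, 1617 to 1676 genes were called for E2, against 2394 in the data. The opposite calls then averaged 7.6 and reached 14 at the highest of 5 simulations. These counts cover the shared libraries alone. They do not show whether 37 exceeds the number that E2 effects unrelated to doxycycline would give.

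Among 366 genes other than ESR2 that doxycycline changed at least 2-fold with E2, at an average log2 CPM of at least 1, the share of the log2 change found without E2 had a median of 30.8% (quartiles 19.9% to 46.5%). In 22 of these genes the share exceeded 75%, among them PDZK1 at 85.2%, complement C3 at 88.8%, the deiodinase DIO2 at 96.0%, ACER1 at 105% and the calcium-binding S100A8 and S100A9 at 88.9% and 86.5%. In 40 genes it was under 10%, and in 13 of these the estimate without E2 had the opposite sign. In size these estimates ran from −0.0196 log2 in FOS to −0.394 log2 in ARID5A. Where the estimate was small, as in FOS and in EGR1 (−0.0807 log2), its sign does not show an opposite response. The libraries numbered 1 and the later ones differed in genes outside the groups, for example CYP1A1 at −1.43, L1CAM at −1.60, ALPP at −1.38, CRISP3 at 1.35 and SOSTDC1 at 0.98 log2 at the later date. Cholesterol synthesis genes were higher at the later date (13 of 23 higher, camera adjusted p = 3.52e-06, and adjusted p = 0.0504 with an estimated correlation) and ATF4 targets lower (17 of 27 lower, adjusted p = 3.15e-09, and adjusted p = 0.0504 with an estimated correlation).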
